A study of Mus musculus with 6 samples.

How the data were processed

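The data were 6 Affymetrix arrays of 22690 probe sets, 1 per sample, hybridised with RNA from pooled DN cells of cultured fetal C57BL/6 thymus lobes. Per the labels, thymocytes came from the lobes and emigrants from buffer flushed off them, culture medium was renewed every 2 days, CD4 and CD8 magnetic beads enriched the DN cells to over 95% as checked by flow cytometry, and RNA was amplified with the Ambion MessageAmp method. Beads against CD4 and CD8 would not take out myeloid or erythroid cells that carry neither marker. The dioxane concentration was given for the thymocyte label alone. Per the submitters' processing notes, the deposited values are RMA summaries, which are background-corrected, normalised across arrays and on the log2 scale, and the series design text names the Bioconductor affy package. The versions used are not given in the sources used here. RMA gives no detection calls and understates the fold changes of dim genes.

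The values were used as deposited. Of the probe sets, 64 controls were left out, 691 with several genes and 1555 without a gene were not tested by gene, and 20380 carried 1 gene symbol. Each gene was represented by its single-gene probe set with the highest mean over the 6 arrays, which gave 12393 genes, 4956 of them with more than 1 probe set. Where probe sets of a named gene differed in sign, the text says so. Members of gene lists without such a probe set are not analysed here.

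The groups were thymocytes with dioxane (1 array), thymocytes with TCDD (1), emigrants with dioxane (2) and emigrants with TCDD (2). Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with 1 prior variance), and p-values were adjusted by the Benjamini-Hochberg method over all genes, with calls at an adjusted p under 0.05. The tested comparisons were TCDD against dioxane in emigrants, TCDD against dioxane over both cell sources with cell source in the model, emigrants against thymocytes with treatment in the model, and the difference of the TCDD effect between the sources. The residual degrees of freedom were 2, 3, 3 and 2, and the median standard errors over genes were 0.288, 0.210, 0.223 and 0.500 log2 units. Models with a lone array assume that it varies like the others. The TCDD difference in thymocytes (1 array each) was given as genes that differed at least 2-fold, and its agreement with emigrants as the share of genes with the same sign among the 100 with the smallest p.

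Gene lists numbered 21: AHR targets, the AHR complex, adhesion and homing, early progenitors (DN1), DN2 and DN3 T lineage, later thymocytes, gamma-delta T cells, NK and innate lymphoid cells, macrophages and dendritic cells, neutrophils and mast cells, B lineage, erythroid cells, thymic epithelium, fibroblasts and endothelium, cell cycle, cell cycle arrest and apoptosis, cytokines and chemokines, immediate-early and stress genes, interferon response, cholesterol synthesis, and hypoxia and glycolysis. Cd44, Egr2 and Il17a each stand in 2 lists. The lists were tested with limma's camera (preset correlation of 0.01), adjusted over the 21 lists, and again with a correlation estimated from the data and with fry. List members were also adjusted over the list alone. For differences between single arrays, each list's median was placed among 10000 random lists of the same size, drawn with the same spread over 20 bins of mean level.

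The genes named in each tested comparison were the 12 largest changes in each direction among called genes, filled up with those of smallest p, which are then said not to have passed; 5 in each direction were named for the difference of effects. In thymocytes these were the 12 largest differences each way whose brighter array reached that array's median. Clone and predicted gene names were counted but not named, and list members were named freely. The lists, models, thresholds and rules were set before the data were examined. The code was tested on simulated data of the same size with 200 changed genes: of 50 genes changed by 2 log2 units it recovered 32, 43, 43 and 0 in the 4 comparisons, and of 50 changed by 4 units 49, 49, 50 and 38, with 6, 8, 13 and 6 false calls. A list shifted by 1 unit was recovered by camera in each comparison, and of the 20 other lists 1, 0, 0 and 1 were called. The simulated noise was independent between genes and had no shared effect of the array number. These counts therefore check the code only and give no error rate for correlated lists. The neutrophil and mast cell list, for example, had an estimated correlation of 0.73 in emigrants.

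Alternatives tried were cyclic loess, median and quantile normalisation, a filter at the median level, an intensity trend in the prior, every probe set on its own, other thresholds, models without covariates or with the array number as a block, and the omission of each array in turn. The omission of both emigrant arrays of a number was added after the data were seen. Leaving out a single emigrant array unbalances the numbers, so that setting mixes the tested difference with part of the difference between the numbers. For TCDD over both sources, leaving out either thymocyte array gives the emigrant fit again. Cell source then takes up the remaining thymocyte array, so these omissions add no new test. No raw array files were analysed here.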

Results

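CD4-CD8- double-negative (DN) cells include the earliest T-cell precursors of the thymus. A DN fraction can also hold other cells that carry neither marker. Gene expression was profiled in DN cells after fetal thymus organ culture of C57BL/6 mouse lobes. In such a culture the isolated lobe goes on making T cells outside the animal. Lobes from day 15 of gestation were kept for 6 days with 10 nM TCDD (2,3,7,8-tetrachlorodibenzo-p-dioxin) or with the solvent, dioxane. TCDD binds the aryl hydrocarbon receptor (AHR), a ligand-activated transcription factor. DN cells were taken either from inside the lobes (thymocytes) or from the fluid flushed off them (emigrants), and RNA of pooled cells was hybridised to 1 Affymetrix array per sample. The groups held 1 thymocyte array with TCDD, 1 thymocyte array with dioxane, 2 emigrant arrays with TCDD and 2 emigrant arrays with dioxane. The emigrant arrays carry the numbers 1 and 2 in the labels, and these numbers name them here. Array medians lay between 4.84 and 4.88 log2 units, and the probe sets for bacterial control transcripts, a guide to the signal without target, had medians of 3.02 to 3.26. The highest of these controls read 4.32 to 4.92, depending on the array. A value under that of its array cannot be told from background, so any difference taken from it is a bound. The number of arrays limits the precision. No source says that arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which can be technical.

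The emigrant arrays numbered 1 stood apart from the other 4 arrays in transcripts of other blood cells. Mpo, the myeloperoxidase of granulocyte precursors, measured 9.83 with dioxane and 10.06 with TCDD on these arrays, and 4.72 to 5.16 on the rest. Ngp, a neutrophil granule protein, measured 12.45 and 12.34 against 6.38 to 9.33, and Alas2, the first enzyme of heme synthesis in red cells, 8.86 and 7.13 against 4.29 to 4.74. Among the dioxane arrays, Dntt, the terminal transferase of rearranging lymphocytes, measured 7.52 in emigrants numbered 1, 11.96 in emigrants numbered 2 and 12.36 in thymocytes. With TCDD it measured 7.65, 5.61 and 9.10. As medians over lists of marker genes, emigrants numbered 1 exceeded emigrants numbered 2 by 1.42 log2 units for neutrophil and mast cell genes, 0.71 for macrophage and dendritic genes and 0.48 for erythroid genes. The same difference was -1.17 for DN2 and DN3 T-lineage genes and -1.80 for gamma-delta T-cell genes. Across genes, the arrays numbered 1 correlated with each other at r = 0.958 and with the other arrays at 0.914 to 0.932. The dioxane thymocyte array and the dioxane emigrant array numbered 2 correlated at 0.966. The 3' minus 5' signal of actin, a guide to RNA quality, was higher with TCDD than with dioxane in each pair: 4.15 against 3.48 in thymocytes, 3.77 against 3.06 in emigrants numbered 1 and 3.36 against 3.01 in emigrants numbered 2. For Gapdh it was 5.86 against 6.10, 5.60 against 4.75 and 4.75 against 4.69. At least 2-fold differences between the dioxane emigrant arrays covered 1554 of 12393 genes, and those between the TCDD emigrant arrays covered 1200. TCDD and dioxane arrays of the same source and number differed that far in 693 to 771 genes.

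**Figure D1:**
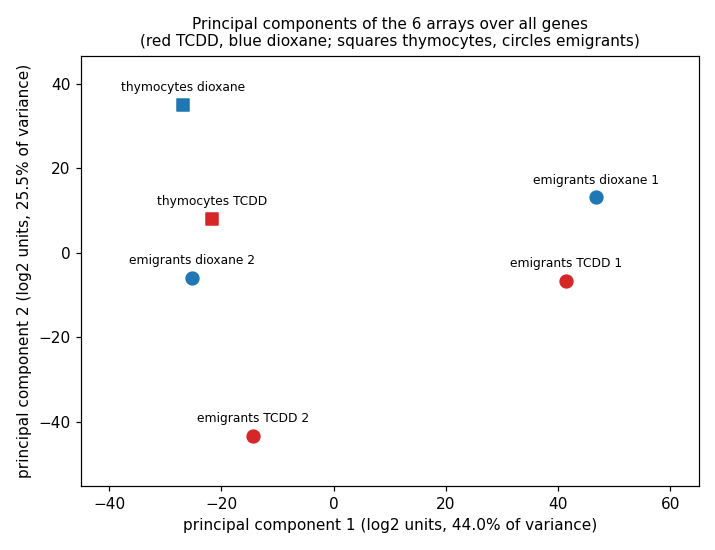
Principal components of the 6 arrays over 12393 genes, with PC1 (44.0% of the variance) on the horizontal axis and PC2 (25.5%) on the vertical axis; each point is an array, red for TCDD and blue for dioxane, squares for thymocytes and circles for emigrants. The emigrant arrays numbered 1 lie at 46.7 (dioxane) and 41.4 (TCDD) on PC1, and the other 4 arrays lie between -26.8 and -14.4.

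**Figure D2:**
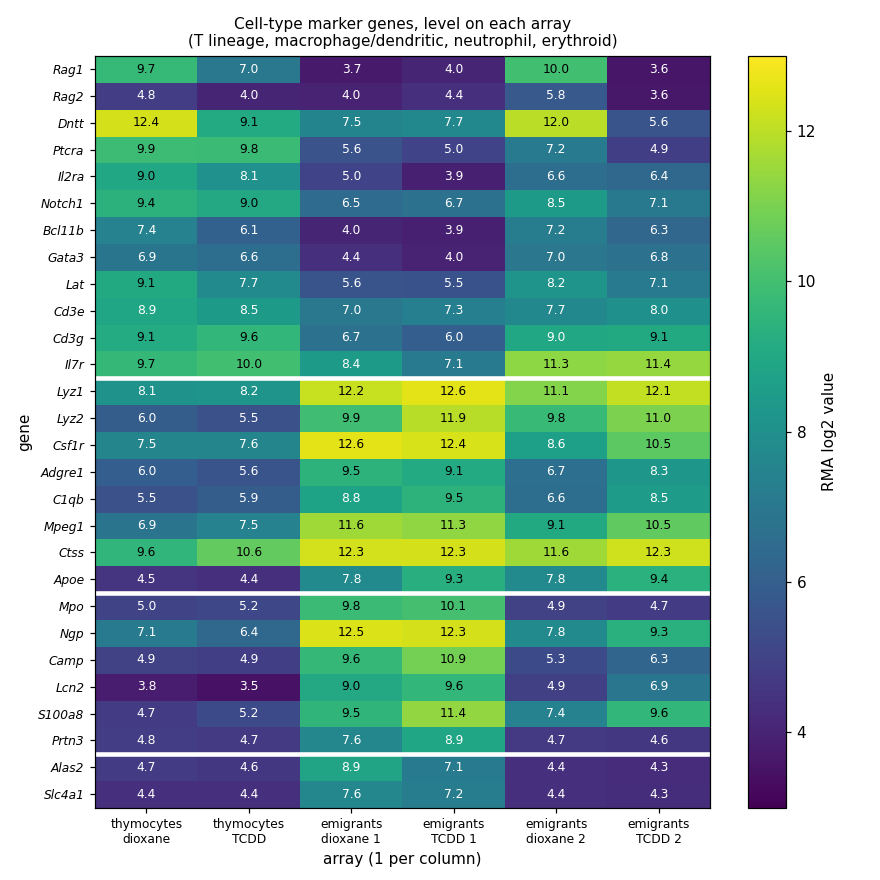
Heat map of RMA log2 values of marker genes for T-lineage, macrophage or dendritic, neutrophil and erythroid cells (vertical axis) on the 6 arrays (horizontal axis), with the colour scale in log2 units. On the emigrant arrays numbered 1 (dioxane, then TCDD) Mpo reads 9.83 and 10.06, Csf1r 12.59 and 12.39 and Alas2 8.86 and 7.13, above the other 4 arrays, while Apoe reads 7.79 and 9.30 there and 7.79 and 9.37 on the emigrant arrays numbered 2.

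The first comparison asked which genes differed with TCDD in the emigrant samples, which also held transcripts of other blood cells (2 emigrant arrays with TCDD against 2 with dioxane). Known AHR targets were higher as a group, with 12 of 15 measured members above dioxane and a median log2 difference of 1.20. Cyp1b1, a monooxygenase that metabolises aromatic compounds, was higher by 2.73 ± 1.03 (log2, SE, n = 2 per group), and Scin, an actin-severing protein, by 1.94 ± 0.35. Tiparp, an ADP-ribosyltransferase that dampens the receptor, differed by 1.75 ± 1.07, Ahrr, its repressor, by 1.66 ± 1.18, and Cyp1a1, the classical inducible monooxygenase, by 1.20 ± 0.62. The list passed limma's camera test against all other genes (adjusted p = 3.22e-05), but not with its own correlation (adjusted p = 0.382 with an estimated correlation). No member passed over all genes, and 1 of the 15 passed adjusted over the list alone (adjusted p = 0.0497). The list's median was 0.24 between the arrays numbered 1 and 1.35 between those numbered 2, pairs in which the actin 3' minus 5' signal was also higher with TCDD (3.77 against 3.06 and 3.36 against 3.01). Ahrr measured 4.45 with dioxane and 4.04 with TCDD in emigrants numbered 1, and 3.76 and 7.50 in emigrants numbered 2. Its values of 4.04 and 3.76 lie under the highest bacterial controls of their arrays (4.92 and 4.45), so its differences are bounded by background. Without the dioxane array numbered 2 the median was 0.42 and the call was lost (adjusted p = 0.183). The median was 0.49 without the TCDD array numbered 1 and 0.24 without the TCDD array numbered 2, and the call held in both.

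**Figure D3:**
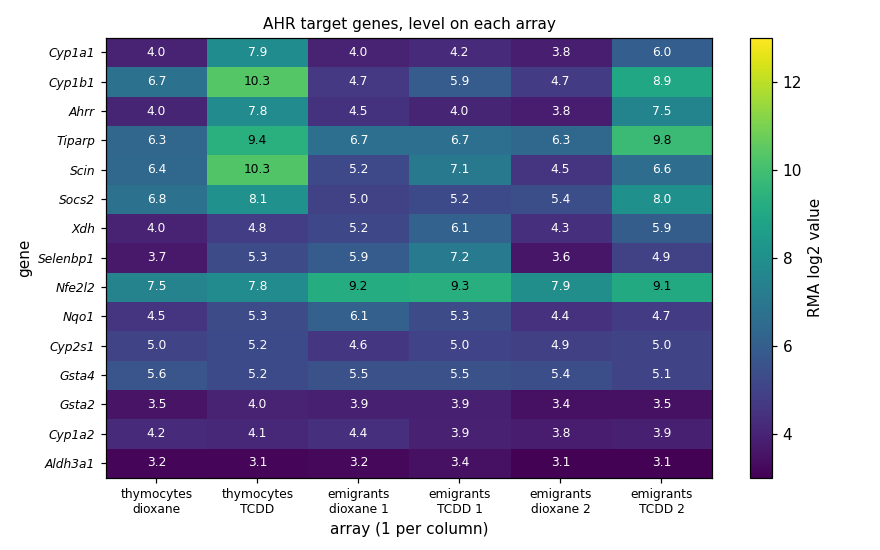
Heat map of RMA log2 values of the 15 measured AHR target genes (vertical axis) on the 6 arrays (horizontal axis), with the colour scale in log2 units. Cyp1a1, Cyp1b1, Ahrr and Tiparp are brighter with TCDD in thymocytes and in emigrants numbered 2 (Tiparp 6.29 against 9.35 and 6.33 against 9.82), while Tiparp reads 6.66 with either treatment in emigrants numbered 1.

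Genes of macrophages and dendritic cells were also higher in TCDD emigrants, in 20 of 21 members, with a median of 0.91 (adjusted p = 1.39e-12; adjusted p = 0.382 with an estimated correlation). Apoe, a lipid carrier of macrophages, was higher by 1.55 ± 0.22, Cst3, a cysteine protease inhibitor, by 1.35 ± 0.22, and Lgals3, a galactose-binding lectin, by 2.36 ± 0.80. Of the 21 members, 2 passed adjusted over the list alone (smallest adjusted p = 0.0241). This list's median was 0.47 within number 1 and 1.31 within number 2, where the Gapdh 3' minus 5' signal with TCDD was 5.60 against 4.75 and 4.75 against 4.69. Neutrophil and mast cell genes had a median of 0.34, with 15 of 19 higher (adjusted p = 0.032; adjusted p = 0.659 with an estimated correlation), and medians of 0.55 within number 1 and 0.11 within number 2. S100a9, a calcium-binding protein of neutrophils, measured 8.37 and 11.39 in emigrants numbered 1 and 7.50 and 9.62 in those numbered 2. Fibroblast and endothelial genes had a median of 0.55, with 15 of 17 higher (adjusted p = 1.77e-05; adjusted p = 0.382 with an estimated correlation), and medians of 0.30 and 1.43 within the numbers. Col3a1, a fibrillar collagen, was higher by 3.35 ± 1.09. Without the dioxane array numbered 2 the macrophage median was 0.21 (adjusted p = 0.0641) and the neutrophil median reversed to -0.36 (adjusted p = 0.565). The neutrophil median was -0.39 without the TCDD array numbered 1 (adjusted p = 0.160), 1.00 without the dioxane array numbered 1 and 1.21 without the TCDD array numbered 2. The neutrophil call also ended with cyclic loess normalisation (0.33, adjusted p = 0.0707) and among genes at or above the median level (0.71, adjusted p = 0.0719). The macrophage median was 1.73 without the dioxane array numbered 1 and 0.48 without the TCDD array numbered 1. The fibroblast median was 1.27 without the TCDD array numbered 1 and 0.22 without the TCDD array numbered 2, and 1.37 among genes at or above the median level, and its call held each time.

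Stress, cytokine and interferon genes shifted upward as well. Immediate-early and stress genes had a median of 0.30 with 16 of 19 higher (adjusted p = 3.22e-05; adjusted p = 0.382 with an estimated correlation), with 0.47 within number 1 and 0.32 within number 2. The 3' minus 5' signal of actin was also higher with TCDD, at 3.77 against 3.06 with dioxane in number 1 and 3.36 against 3.01 in number 2. Egr2, a zinc-finger factor induced by antigen-receptor signals, was higher by 1.69 ± 0.24 and passed adjusted over the list alone (adjusted p = 0.0241), and Atf3, a stress-induced transcription factor, differed by 1.67 ± 0.39. Cytokine and chemokine genes had a median of 0.26 with 15 of 18 higher (adjusted p = 0.00345; adjusted p = 0.382 with an estimated correlation), with 0.20 and 0.37 within the numbers. Ccl3, a chemokine for monocytes, differed by 2.26 ± 0.81. Ifng, the cytokine of type 1 responses, ran the other way at -1.36 ± 0.34. Interferon-response genes had a median of 0.52 with 10 of 12 higher (adjusted p = 0.00341; adjusted p = 0.583 with an estimated correlation), but -0.08 within number 1 and 1.05 within number 2. Hypoxia and glycolysis genes had a median of 0.36 with 12 of 15 higher (adjusted p = 0.00106; adjusted p = 0.382 with an estimated correlation), with 0.37 and 0.22 within the numbers. Slc2a1, the main glucose transporter, differed by 2.03 ± 0.54. The cytokine call was lost without the dioxane array numbered 1 (0.21, adjusted p = 0.0590), the dioxane array numbered 2 (0.30, adjusted p = 0.0641) or the TCDD array numbered 2 (0.29, adjusted p = 0.107). Among genes at or above the median level the cytokine call ended as well (0.34, adjusted p = 0.180). The interferon median was 0.23 without the dioxane array numbered 1, 0.73 without the dioxane array numbered 2 (adjusted p = 0.158), 1.37 without the TCDD array numbered 1, and -0.38 without the TCDD array numbered 2 (adjusted p = 0.400). Without the dioxane array numbered 2, the median of the immediate-early genes was 0.46 and that of the hypoxia genes 0.12, and both calls held.

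T-lineage, proliferation and sterol genes shifted downward in TCDD emigrants, the arrays with the higher actin 3' minus 5' signal (3.77 against 3.06 and 3.36 against 3.01). DN2 and DN3 T-lineage genes had a median of -0.36, with 19 of 22 lower (adjusted p = 0.0259; adjusted p = 0.637 with an estimated correlation), and -0.12 within number 1 against -0.43 within number 2. Rag1, which cuts DNA in receptor gene rearrangement, measured 9.99 with dioxane and 3.61 with TCDD in emigrants numbered 2, but 3.72 and 4.03 in those numbered 1. The last 3 values lie under the highest bacterial control of their arrays (4.32 to 4.92). Later thymocyte genes had a median of -0.43 with 11 of 15 lower (adjusted p = 0.00699; adjusted p = 0.421 with an estimated correlation), with -0.00 and -0.73 within the numbers. Cd28, a costimulatory receptor, differed by -1.41 ± 0.71. Cell cycle genes had a median of -0.46 with 24 of 28 lower (adjusted p = 3.42e-06; adjusted p = 0.583 with an estimated correlation), with 0.01 and -1.12 within the numbers. Aurkb, a mitotic kinase, differed by -0.99 ± 0.36. Cholesterol synthesis genes had a median of -0.52 with 11 of 12 lower (adjusted p = 0.00699; adjusted p = 0.583 with an estimated correlation), with 0.03 and -1.10 within the numbers. Hmgcs1, an early enzyme of the pathway, measured 11.20 and 9.48 in emigrants numbered 2. Without the dioxane array numbered 2 the medians were 0.16 for DN2 and DN3 genes (adjusted p = 0.494), -0.07 for later thymocyte genes (adjusted p = 0.565), -0.30 for cell cycle genes (adjusted p = 0.213) and 0.08 for cholesterol genes (adjusted p = 0.565). The DN2 and DN3 median was -0.03 without the TCDD array numbered 1 (adjusted p = 0.719), and the cell cycle median was -0.17 without the TCDD array numbered 2 (adjusted p = 0.234). Among genes at or above the median level the later thymocyte call ended (-0.43, adjusted p = 0.140). Other omissions kept the call but moved a median. They gave -1.52 (DN2 and DN3), -0.87 (later thymocyte) and -1.21 (cholesterol) without the dioxane array numbered 1, -0.82 (cell cycle) and -0.35 (cholesterol) without the TCDD array numbered 1, and -1.21 (DN2 and DN3) without the TCDD array numbered 2.

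Single genes with the smallest p in emigrants were led by myeloid and chemokine transcripts. Clec4d, a C-type lectin of myeloid cells, was higher by 2.88 ± 0.29, Ccl9 and Ccl6, macrophage chemokines, by 2.65 ± 0.27 and 1.72 ± 0.24, and Cxcl2 and Cxcl1, neutrophil attractants, by 3.87 ± 0.64 and 2.65 ± 0.31. Ms4a6d (2.25 ± 0.24), Anxa3 (2.63 ± 0.31), Cstb (1.63 ± 0.24) and Ifi30 (1.65 ± 0.25) were also higher. On the lower side stood Cmtm7 (-1.89 ± 0.24), Slamf6, a lymphocyte adhesion receptor (-1.32 ± 0.25), Chek1, the replication checkpoint kinase (-1.34 ± 0.24), and Ncapg2, a condensin subunit (-1.31 ± 0.26). Atp1b1 (-1.65 ± 0.26), Nfyb (-1.54 ± 0.24), Qser1 (-1.33 ± 0.24), Srsf2 (-1.21 ± 0.23), Anp32e (-1.63 ± 0.31), Prpf4b (-1.28 ± 0.26), Sinhcaf (-1.09 ± 0.22) and B3gnt2 (-1.05 ± 0.22) completed that side. The probe sets of Cmtm7, Atp1b1, Chek1, Prpf4b and B3gnt2 differed in sign. Cxcl1 read 4.24 and 4.08 on the dioxane emigrant arrays, under the highest bacterial controls there (4.32 and 4.45). Qser1 read 4.29 on TCDD emigrant array 1, also under the highest control of its array (4.92). Their differences, and those of any gene in this position, are bounded by background. The fit had no term for the array number, so the difference between the numbers stayed in its residual spread and can hide TCDD differences. None of these genes passed: limma called 0 of 12393 genes (smallest adjusted p = 1.00), with 255 genes at an unadjusted p under 0.05 (154 higher, 101 lower), where 620 would come by chance. Of the remaining lists, the AHR complex (-0.23, adjusted p = 0.182), NK and innate lymphoid (0.28, adjusted p = 0.461), B lineage (-0.10, adjusted p = 0.611), thymic epithelium (-0.08, mean 0.02, adjusted p = 0.5004) and cell cycle arrest and apoptosis (-0.08, mean 0.03, adjusted p = 0.783) did not pass, with or without any single array. Adhesion and homing genes (0.09, adjusted p = 0.182) passed without the TCDD array numbered 1 (0.28, adjusted p = 0.0241), as did erythroid genes (-0.14, adjusted p = 0.655; then -0.52, adjusted p = 0.0153). Early progenitor (DN1) genes (0.26, adjusted p = 0.102) passed without the dioxane array numbered 1 (0.54, adjusted p = 8.77e-05) or the TCDD array numbered 2 (0.47, adjusted p = 0.0290). Gamma-delta T-cell genes had a median of 0.20 (adjusted p = 0.0914; adjusted p = 0.659 with an estimated correlation). Their median was 1.12 without the dioxane array numbered 2 and 1.81 without the TCDD array numbered 1. Each of these omissions leaves 1 array in a group and unbalances the numbers.

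Across both cell sources (3 arrays with TCDD against 3 with dioxane, cell source in the fit), AHR targets were again higher, in 13 of 15 members, with a median of 1.11 (adjusted p = 3.98e-06; adjusted p = 0.237 with an estimated correlation). Cyp1b1 was higher by 3.03 ± 0.78, Tiparp by 2.18 ± 0.84, Cyp1a1 by 2.09 ± 0.71 and Xdh, xanthine dehydrogenase, by 1.11 ± 0.27, and 3 of 15 members passed adjusted over the list alone (smallest adjusted p = 0.0287). Cell cycle genes were lower in 26 of 28 members, with a median of -0.59 (adjusted p = 1.49e-09; adjusted p = 0.402 with an estimated correlation), among them Mki67, the proliferation marker, at -1.16 ± 0.37 and Mcm4, part of the replicative helicase, at -0.69 ± 0.22. Within the pairs of arrays the cell cycle median was -0.58 in thymocytes, 0.01 in emigrants numbered 1 and -1.12 in emigrants numbered 2, and the AHR target median was 0.82, 0.24 and 1.35. In the same pairs the actin 3' minus 5' signal with TCDD was 4.15 against 3.48, 3.77 against 3.06 and 3.36 against 3.01, beside each list given here for both sources. For Gapdh it was 5.86 against 6.10, 5.60 against 4.75 and 4.75 against 4.69. Macrophage and dendritic genes were higher in 20 of 21 (median 0.86, adjusted p = 7.58e-10; adjusted p = 0.356 with an estimated correlation), with 0.19, 0.47 and 1.31 within the pairs. H2-Eb1, a class II antigen-presenting chain, differed by 1.24 ± 0.21 and Lgals3 by 2.78 ± 0.64, and 3 of 21 members passed adjusted over the list alone (smallest adjusted p = 0.0263). Without the TCDD emigrant array numbered 2 the AHR target median was 0.58 and the cell cycle median -0.32. The median of AHR targets was 1.79 among genes at or above the median level. The macrophage median was 0.33 without the dioxane emigrant array numbered 2 and 0.55 without the TCDD emigrant array numbered 1. These calls held in every omission of 1 array. Without either thymocyte array the fit is that of the emigrants given above, so those omissions are no separate check.

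Cytokine genes (median 0.23, 16 of 18 higher, adjusted p = 0.00098; adjusted p = 0.237 with an estimated correlation) and immediate-early genes (0.26, 18 of 19 higher, adjusted p = 6.15e-05; adjusted p = 0.237 with an estimated correlation) also kept their calls in every omission of 1 array. Within thymocytes, emigrants numbered 1 and emigrants numbered 2 the cytokine medians were 0.27, 0.20 and 0.37, and the immediate-early medians 0.29, 0.47 and 0.32. Fos, an immediate-early factor, differed by 0.74 ± 0.22, and Il2, the T-cell growth factor, by 0.53 ± 0.15. The immediate-early median was 0.41 without the TCDD emigrant array numbered 1 and 0.47 without the TCDD emigrant array numbered 2. Cholesterol synthesis genes were lower in 12 of 12 (median -0.58, adjusted p = 0.000892; adjusted p = 0.402 with an estimated correlation), with -0.68, 0.03 and -1.10 within the pairs. Lss, a cyclase of the pathway, differed by -0.85 ± 0.28. That call was lost without the dioxane emigrant array numbered 2 (-0.22, adjusted p = 0.113), and the median was -1.02 without the dioxane emigrant array numbered 1. DN2 and DN3 genes were lower in 18 of 22 (median -0.39, adjusted p = 0.0234; adjusted p = 0.572 with an estimated correlation), with -0.33, -0.12 and -0.43 within the pairs. Later thymocyte genes were lower in 11 of 15 (median -0.28, adjusted p = 0.0158; adjusted p = 0.402 with an estimated correlation), with -0.08, -0.00 and -0.73 within the pairs. Both T-lineage calls were lost without the dioxane emigrant array numbered 2 (-0.02, adjusted p = 0.663, and -0.10, adjusted p = 0.277) and without the TCDD emigrant array numbered 1 (-0.09, adjusted p = 0.436, and -0.22, adjusted p = 0.0695). The DN2 and DN3 median was -1.03 without the dioxane emigrant array numbered 1 and -0.76 without the TCDD emigrant array numbered 2, and the later thymocyte median was -0.43 without either thymocyte array. Among genes at or above the median level, the later thymocyte (-0.07, adjusted p = 0.202) and cytokine calls (0.32, adjusted p = 0.107) ended. The DN2 and DN3 call ended without cell source in the model (adjusted p = 0.0659).

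Adhesion, homing and emigration genes had a median of 0.22 with 19 of 25 higher (adjusted p = 0.0136; adjusted p = 0.321 with an estimated correlation), and 0.41, 0.03 and 0.13 within the pairs. Cd9, a tetraspanin, differed by 1.96 ± 0.33 and was the member that passed adjusted over the list alone (adjusted p = 0.0335), and S100a4, a calcium-binding motility protein, differed by 2.05 ± 0.79. NK and innate lymphoid genes had a median of 0.35 with 14 of 17 higher (adjusted p = 0.00233; adjusted p = 0.402 with an estimated correlation), and 1.35, 0.03 and 0.24 within the pairs. Id2, an inhibitor of E proteins, differed by 1.48 ± 0.47. Neither list passed without either thymocyte array, which gives the emigrant fit again (0.09, adjusted p = 0.182, and 0.28, adjusted p = 0.461). Both calls thus needed the thymocyte pair. Without the TCDD emigrant array numbered 2 the adhesion call was lost (0.17, adjusted p = 0.0693). Fibroblast and endothelial genes had a median of 0.39 with 15 of 17 higher (adjusted p = 0.00357; adjusted p = 0.409 with an estimated correlation), and -0.05, 0.30 and 1.43 within the pairs. That call was lost without the emigrant array numbered 2 of either treatment (dioxane 0.33, adjusted p = 0.0928; TCDD 0.15, adjusted p = 0.196). Among genes at or above the median level the fibroblast median was 0.95 and the adhesion median 0.52, and both calls held. Interferon-response genes had a median of 0.36 with 11 of 12 higher (adjusted p = 0.00337; adjusted p = 0.506 with an estimated correlation), and 0.34, -0.08 and 1.05 within the pairs. Ifit1, an interferon-induced antiviral protein, differed by 1.42 ± 0.35. The interferon median was -0.10 without the TCDD emigrant array numbered 2 (adjusted p = 0.746). Without the TCDD emigrant array numbered 1 the medians were 0.44 for adhesion, 0.61 for NK and 0.82 for interferon genes, and without the dioxane emigrant array numbered 2 the adhesion median was 0.32, with the calls kept.

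With both emigrant arrays numbered 1 left out, a setting added after the data were seen, gamma-delta T-cell genes passed as well (median 0.63 over all arrays, adjusted p = 0.0713; then 0.80, adjusted p = 0.000113), as they did without the dioxane emigrant array numbered 2 (1.30, adjusted p = 0.00295) or the TCDD emigrant array numbered 1 (1.24, adjusted p = 0.000106). Within the pairs their median was 0.60, 0.03 and 0.78. The genes with the smallest p over both sources were Cmtm7 (-1.87 ± 0.16, adjusted p = 0.483), Dhrs7, a short-chain dehydrogenase (1.19 ± 0.14, adjusted p = 0.742), Slamf6 (-1.29 ± 0.16) and Ifi30, a lysosomal thiol reductase (1.48 ± 0.20). Higher values were also found for Acyp2 (1.46 ± 0.24), Cxcl2 (3.31 ± 0.58), Necap2 (0.96 ± 0.17), Srd5a3 (0.86 ± 0.15), Mapre2 (0.85 ± 0.15), Golm1 (0.82 ± 0.15) and Tmem208 (1.09 ± 0.20). Lower values were found for Anp32e (-1.61 ± 0.22), Qser1 (-1.59 ± 0.22), B3gnt2 (-1.23 ± 0.17), Chek1 (-1.21 ± 0.17), Fbxo45 (-1.13 ± 0.16), Nfyb (-1.35 ± 0.20), Rad23b (-0.91 ± 0.14), Naa15 (-1.31 ± 0.21) and the mitosis genes Nusap1 (-1.37 ± 0.22) and Ncapg2 (-1.17 ± 0.19). The probe sets of Cmtm7, B3gnt2, Chek1, Mapre2 and Rad23b differed in sign. As in emigrants alone, the difference of Qser1 is bounded by background. None passed: limma called 0 of 12393 genes, with 659 at an unadjusted p under 0.05 (333 higher, 326 lower) and 620 by chance. That number was 2065 with the emigrant arrays numbered 1 left out, again with 0 genes called (smallest adjusted p = 0.128). The AHR complex (-0.17, adjusted p = 0.177), B lineage (-0.06, adjusted p = 0.751), erythroid (-0.07, adjusted p = 0.751) and thymic epithelium lists (-0.02, mean 0.06, adjusted p = 0.751) did not pass. Early progenitor (0.12, adjusted p = 0.0935), neutrophil and mast cell (0.23, adjusted p = 0.113), arrest and apoptosis (-0.02, mean 0.10, adjusted p = 0.353) and hypoxia genes (0.06, adjusted p = 0.330) did not pass over all arrays. Each of these lists passed in at least 1 omission. Early progenitor genes gave 0.52 (adjusted p = 0.00332), neutrophil genes 0.44 (adjusted p = 0.0108) and arrest genes 0.08 (adjusted p = 0.0292) without the dioxane emigrant array numbered 1. Early progenitor genes gave 0.51 (adjusted p = 0.0315) and neutrophil genes 0.59 (adjusted p = 0.000909) without the TCDD emigrant array numbered 2. Without either thymocyte array, which gives the emigrant fit again, neutrophil genes gave 0.34 (adjusted p = 0.0320) and hypoxia genes 0.36 (adjusted p = 0.00106).

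In thymocytes inside the lobes, the TCDD array was set against the dioxane array, 1 array each, so these differences have no replicate check and no p-value. The actin 3' minus 5' signal was 4.15 with TCDD and 3.48 with dioxane, while that of Gapdh was 5.86 and 6.10. The AHR targets were higher by a median of 0.82, above each of 10000 random lists of like size and level, and 7 of 15 exceeded 2-fold. Cyp1a1 measured 3.99 with dioxane and 7.88 with TCDD, Cyp1b1 6.73 and 10.35, Ahrr 4.05 and 7.84, and Scin 6.37 and 10.30. The dioxane values of Cyp1a1 and Ahrr lie under the highest bacterial control of that array (4.72), so their differences are bounded by background. The NK and innate lymphoid list was higher by a median of 1.35. Its members include Gzmb, a cytotoxic granule protease, at 6.11 and 10.22 and Ccl5, a chemokine of effector lymphocytes, at 7.61 and 11.28. The median was -0.68 for cholesterol synthesis and -0.58 for the cell cycle list. Rag1 measured 9.70 and 7.00, Dntt 12.36 and 9.10, and Rag2, the partner of Rag1, 4.82 and 4.05, the latter under the highest bacterial control of its array (4.46). Other large differences on the higher side were found for Dsp (4.49), Jchain, the joining chain of secreted immunoglobulins (4.12), Car2, a carbonic anhydrase (3.89), Cpd (3.74), Lgals3 (3.64) and Serpinb1a, a protease inhibitor (3.43). Jchain read under the highest bacterial control of the dioxane array (4.72) there. Its difference, and that of any gene in this position, is bounded by background. On the lower side stood Slc16a1, a lactate transporter (-3.36), Gins1, part of the replicative helicase (-2.72), Bex1 (-2.66), Naf1 (-2.64), Endou (-2.60), Khdc1a (-2.56) and Smo, a Hedgehog pathway receptor (-2.46). Asns (-2.65), Bcat1 (-2.37) and Shmt2 (-2.35), enzymes of amino acid and one-carbon metabolism, were lower too. The probe sets of Dsp and Cpd differed in sign.

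Among the other lists in thymocytes, gamma-delta T-cell genes were higher by a median of 0.60 (percentile 100 of the random lists), adhesion genes by 0.41 (99.99), interferon genes by 0.34 (99.53), immediate-early genes by 0.29 (99.77), cytokine genes by 0.27 (99.98) and arrest and apoptosis genes by 0.27 (99.88). DN2 and DN3 genes had a median of -0.33 (percentile 0.46) and hypoxia genes -0.32 (1.01). Macrophage genes, at 0.19 (95.33), neutrophil genes, at -0.06 (22.52), fibroblast genes, at -0.05 (23.32), later thymocyte genes, at -0.08 (17.14), and early progenitor genes, at 0.14 (93.02), lay inside the middle 95% of random lists. Differences of at least 2-fold covered 697 of 12393 genes (351 higher, 346 lower). The same count was 1554 between the dioxane emigrant arrays and 1200 between the TCDD emigrant arrays. Those arrays differ in number, and with it in the blood-cell transcripts given above, so they give no replicate spread for thymocytes. Whether 697 exceeds that spread is not known. Of the 100 genes with the smallest p in emigrants, 85 differed in the same direction in thymocytes (exact 95% interval 76.5% to 91.4%, for counting error only and treating genes as independent). Across all 12393 genes the share was 57.8%. Across genes, which are not independent replicates, the thymocyte differences correlated with those of emigrants numbered 2 at r = 0.526 (Spearman's rho 0.425) and with those of emigrants numbered 1 at 0.101 (rho 0.0740). The differences of the 2 emigrant pairs correlated at 0.143 (rho 0.0804).

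**Figure D4:**
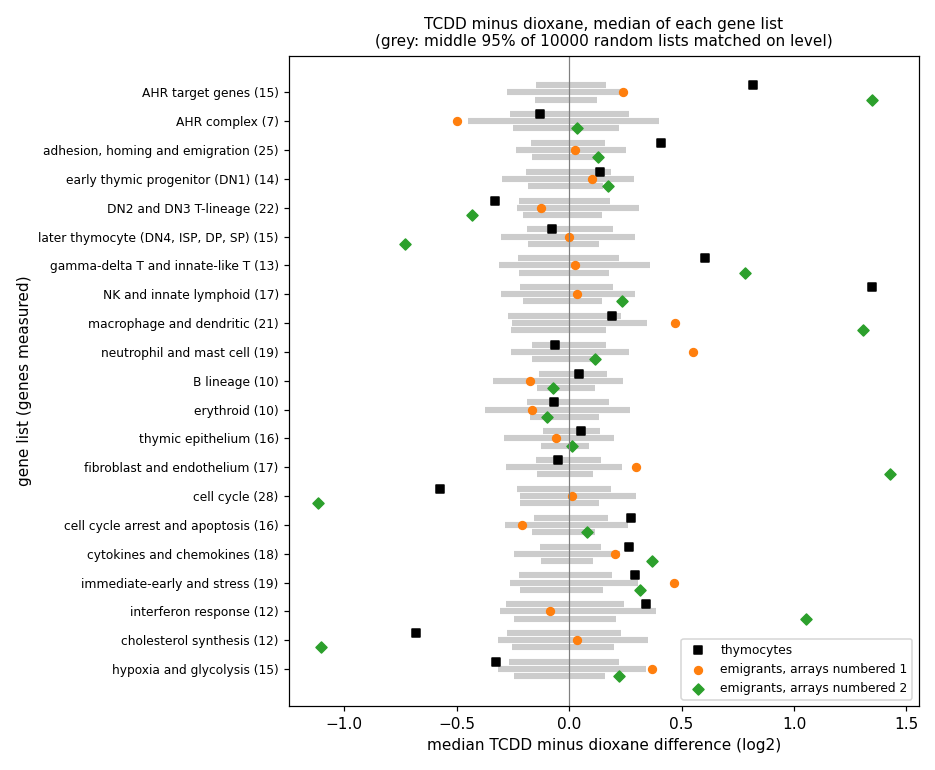
Median log2 difference, TCDD minus dioxane (horizontal axis), of each of the 21 gene lists (vertical axis) in thymocytes (black squares), emigrants numbered 1 (orange circles) and emigrants numbered 2 (green diamonds), 1 array per treatment in each pair, with grey bars for the middle 95% of 10000 random lists. AHR targets lie at 0.82, 0.24 and 1.35, cell cycle genes at -0.58, 0.01 and -1.12, and NK genes at 1.35, 0.03 and 0.24.

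Emigrants were compared with thymocytes over both treatments (4 arrays against 2) to find what set the emigrant samples apart. Macrophage and dendritic genes were higher in all 21 members, by a median of 2.12 (adjusted p = 1.01e-23; adjusted p = 0.469 with an estimated correlation), and 14 of 21 passed adjusted over the list alone (smallest adjusted p = 0.000697). Lyz2, the macrophage lysozyme, was higher by 4.94 ± 0.53, Apoe by 4.11 ± 0.38 and Lyz1 by 3.85 ± 0.36. Apoe read 4.40 with TCDD and 4.51 with dioxane in thymocytes, under the highest bacterial controls there (4.46 and 4.72), so its difference is bounded by background. DN2 and DN3 genes were lower in 19 of 22, by a median of -1.03 (adjusted p = 2.53e-07; adjusted p = 0.476 with an estimated correlation), and 5 of 22 passed adjusted over the list alone (smallest adjusted p = 0.00749). Ptcra, the pre-T-cell receptor alpha chain, differed by -4.20 ± 0.53, Il2ra, the interleukin-2 receptor alpha chain of DN2 and DN3 cells, by -3.07 ± 0.78, and Notch1 by -2.04 ± 0.54. Neutrophil and mast cell genes were higher in 15 of 19, by a median of 0.83 (adjusted p = 4.19e-05; adjusted p = 0.699 with an estimated correlation), and 2 of 19 passed adjusted over the list alone. S100a8 differed by 4.52 ± 0.80. The Gapdh 3' minus 5' signal also differed between the sources, at 5.86 and 6.10 in thymocytes and 4.69 to 5.60 on the 4 emigrant arrays. It was close between dioxane emigrants numbered 1 and 2 (4.75 and 4.69), which differed in these lists. The actin 3' minus 5' signal was 3.48 in dioxane thymocytes against 3.06 and 3.01 in dioxane emigrants. With TCDD it was 4.15 in thymocytes against 3.77 and 3.36 in emigrants. Between the dioxane arrays alone, the macrophage median was 2.73 for emigrants numbered 1 and 1.10 for emigrants numbered 2 (21 of 21 higher), the neutrophil median was 2.14 and -0.02, and the DN2 and DN3 median was -1.99 and -0.29. These 3 calls held in every omission of 1 array, with a neutrophil median of 1.39 without the dioxane emigrant array numbered 2, 0.32 without the TCDD emigrant array numbered 1 and 1.34 without the TCDD emigrant array numbered 2. The neutrophil median was 2.28 among genes at or above the median level. With both emigrant arrays numbered 1 left out, the macrophage call held, the DN2 and DN3 median was -0.67 (adjusted p = 0.107) and the neutrophil median was -0.08 (adjusted p = 0.538).

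Cholesterol synthesis genes were lower in emigrants, where the Gapdh 3' minus 5' signal was 4.69 to 5.60 against 5.86 and 6.10, in 9 of 12, by a median of -0.92 (adjusted p = 0.000569; adjusted p = 0.634 with an estimated correlation), with dioxane medians of -1.83 for emigrants numbered 1 and -0.36 for those numbered 2. Fdft1, squalene synthase, differed by -2.10 ± 0.75. The median was -0.59 without the dioxane emigrant array numbered 1 and -0.55 without both arrays numbered 1, and the call held in each. Fibroblast and endothelial genes were lower in 14 of 17, by a median of -0.73 (adjusted p = 0.00701; adjusted p = 0.691 with an estimated correlation), with dioxane medians of -0.83 and -1.03, and Col1a2, a fibrillar collagen, differed by -1.80 ± 0.70. That call was lost without the dioxane thymocyte array (-0.14, adjusted p = 0.547), the dioxane emigrant array numbered 1 (-0.74, adjusted p = 0.0515) or numbered 2 (-0.59, adjusted p = 0.0665), and the median was -0.45 without the TCDD emigrant array numbered 1. Among genes at or above the median level the fibroblast (-0.39, adjusted p = 0.356) and epithelium calls (0.01, adjusted p = 0.704) ended. Thymic epithelium genes were lower in 13 of 16, by a median of -0.20 (adjusted p = 0.0197; adjusted p = 0.469 with an estimated correlation), and Epcam, an epithelial adhesion molecule, differed by -1.74 ± 0.32. The epithelium call was lost without the TCDD thymocyte array (-0.17, adjusted p = 0.137), the dioxane emigrant array numbered 2 (-0.20, adjusted p = 0.0665) or the TCDD emigrant array numbered 1 (-0.16, adjusted p = 0.0525). Adhesion and homing genes were higher in 17 of 25, by a median of 0.19 (adjusted p = 0.0264; adjusted p = 0.469 with an estimated correlation), with Itgb2, a leukocyte integrin chain that myeloid cells share, at 1.81 ± 0.33 and Cd9 at 2.13 ± 0.35. Of the 25 members, 2 passed adjusted over the list alone. The adhesion call was lost without the dioxane thymocyte array (0.02, adjusted p = 0.469), the dioxane emigrant array numbered 2 (0.09, adjusted p = 0.163) or the TCDD emigrant array numbered 2 (0.10, adjusted p = 0.0669). The adhesion median was 0.29 without the TCDD thymocyte array and 0.32 among genes at or above the median level. The adhesion call ended without treatment in the model (adjusted p = 0.0611) and with the array number as a block.

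Among the genes with the smallest p between the sources, higher values were found for Plek, a platelet and leukocyte protein (3.29 ± 0.39), Ccl6 (4.51 ± 0.55), Anxa1 (3.10 ± 0.43), Ctss, a lysosomal protease of antigen-presenting cells (2.03 ± 0.28), Abca1, a cholesterol exporter (2.33 ± 0.26), Sirpa, a myeloid inhibitory receptor (2.68 ± 0.37), Gpr137b (1.85 ± 0.22), Ifi30 (1.65 ± 0.21) and Cyrib (1.17 ± 0.16). Lower values were found for Mpzl2, an adhesion protein (-3.63 ± 0.26, adjusted p = 0.165), B4galnt2, a glycosyltransferase (-2.18 ± 0.19), Rnf157 (-2.34 ± 0.22), Tle3, a Groucho-type corepressor (-1.85 ± 0.25), Igf2, a fetal growth factor (-1.82 ± 0.24), Bcl9l (-1.21 ± 0.19), Nrep (-2.49 ± 0.39), Csn2 (-2.06 ± 0.32), Col6a2 (-2.34 ± 0.38), Cnpy2 (-1.27 ± 0.21) and Egr1 (-1.52 ± 0.25). The probe sets of Abca1, Sirpa, Gpr137b and Cnpy2 differed in sign. Where a gene read under the highest bacterial control of its arrays in 1 source, its difference is a bound set by background. None passed: limma called 0 of 12393 genes, with 880 at an unadjusted p under 0.05 (397 higher, 483 lower) and 620 by chance. Without the dioxane emigrant array numbered 2, 7 genes passed (4 higher, 3 lower). With both emigrant arrays numbered 2 left out, a setting added after the data were seen, 225 genes passed (163 higher, 62 lower), and with both numbered 1 left out, 0 passed, with 2571 at an unadjusted p under 0.05. Lists that did not pass over all arrays were AHR targets (-0.16, adjusted p = 0.522; 1 of 15 passed adjusted over the list alone, adjusted p = 0.0469), the AHR complex (-0.10, adjusted p = 0.843), later thymocyte (0.02, mean -0.09, adjusted p = 0.661), B lineage (0.02, adjusted p = 0.614), arrest and apoptosis (-0.05, adjusted p = 0.661), cytokines (-0.02, adjusted p = 0.843) and immediate-early genes (-0.07, adjusted p = 0.406), in which 1 member, Egr1, passed adjusted over the list alone (adjusted p = 0.0240). Early progenitor (0.12, adjusted p = 0.406) and erythroid genes (0.04, adjusted p = 0.788) passed with the emigrant arrays numbered 2 left out (0.22, adjusted p = 0.00298, and 0.27, adjusted p = 0.0112). Gamma-delta T-cell genes (-0.01, adjusted p = 0.943) passed upward with the arrays numbered 1 left out (0.52, adjusted p = 0.000281) and downward with those numbered 2 left out (-1.11, adjusted p = 0.00133). Interferon genes (0.07, adjusted p = 0.522) passed without the TCDD emigrant array numbered 1 (0.35, adjusted p = 0.0187). NK genes (0.17, adjusted p = 0.123) passed without the TCDD thymocyte array (0.75, adjusted p = 1.76e-06) or the TCDD emigrant array numbered 1 (0.39, adjusted p = 0.0159), and hypoxia genes (-0.05, adjusted p = 0.614) passed without the TCDD thymocyte array (-0.46, adjusted p = 0.000341). Cell cycle genes (0.01, adjusted p = 0.406) passed without the dioxane emigrant array numbered 1 (0.13, adjusted p = 0.0266) or the TCDD emigrant array numbered 2 (0.15, adjusted p = 0.0221).

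Whether the TCDD effect itself differed between emigrants and thymocytes was tested as an interaction over all 6 arrays. NK and innate lymphoid genes had a smaller TCDD difference in emigrants in 15 of 17 members, by a median of -1.39 (adjusted p = 2.65e-08; adjusted p = 0.288 with an estimated correlation). For Ccl5 the difference of the effects was -3.32 ± 0.88 and for Nkg7, a cytotoxic granule protein, -2.11 ± 1.00. Without TCDD the NK list was already higher in emigrants. Its median over the dioxane thymocyte array was 0.46 for emigrants numbered 1 and 1.06 for those numbered 2. Fibroblast and endothelial genes had a larger difference in emigrants in 13 of 17, by a median of 0.76 (adjusted p = 1.90e-05; adjusted p = 0.726 with an estimated correlation), with Col3a1 at 3.38 ± 1.88 and Postn, a matrix protein, at 2.38 ± 1.10. Hypoxia and glycolysis genes had a larger difference in 12 of 15, by a median of 0.75 (adjusted p = 2.96e-07; adjusted p = 0.288 with an estimated correlation), with Bnip3, a mitophagy receptor, at 2.00 ± 0.48 and Aldoa, a glycolytic aldolase, at 1.86 ± 0.45. The Gapdh 3' minus 5' signal also differed between the sources in its TCDD change, with 5.86 for TCDD against 6.10 for dioxane in thymocytes, 5.60 against 4.75 in emigrants numbered 1 and 4.75 against 4.69 in emigrants numbered 2. These 3 calls held in every omission of 1 emigrant array. The lone thymocyte arrays could not be left out, so dependence on either of them is untested. The fibroblast median was 0.38 without the TCDD array numbered 2 and 1.46 among genes at or above the median level, and the hypoxia median 0.49 without the TCDD array numbered 1. AHR targets (-0.32, adjusted p = 0.112) did not pass over all arrays, but passed without the dioxane array numbered 2 (-0.61, adjusted p = 0.0215) or the TCDD array numbered 2 (-0.20, adjusted p = 9.91e-05). Of the lists that passed without 1 array, 3 passed in opposite directions in different omissions. DN2 and DN3 genes gave -0.88 without the dioxane array numbered 1 and 0.82 without that numbered 2, and cholesterol genes -0.28 and 0.70. Without the dioxane array numbered 1, later thymocyte (-0.45), adhesion (-0.30), early progenitor (0.53), macrophage (1.12) and neutrophil genes (1.33) passed too, and without the dioxane array numbered 2, cell cycle (0.45) and arrest genes (-0.27). Interferon genes passed at 0.66 without the TCDD array numbered 1 and at -0.64 without that numbered 2. Without the TCDD array numbered 2, gamma-delta (-1.41), adhesion (-0.50), macrophage (0.91), neutrophil (1.44) and cell cycle genes (0.52) passed as well. The number of lists that passed was 3 over all arrays, 10 without the dioxane array numbered 1, 8 without the dioxane array numbered 2, 4 without the TCDD array numbered 1 and 10 without the TCDD array numbered 2.

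Single genes with the largest evidence of a different TCDD effect were Ccl9 (3.17 ± 0.47), Ccl6 (2.48 ± 0.42), Clec4d (2.89 ± 0.51), Ms4a6d (1.95 ± 0.42) and Igfbp4, a binding protein of insulin-like growth factors (2.09 ± 0.43), higher in emigrants. Cntnap2 (-3.25 ± 0.52), the adhesion genes Cdh1 (-3.43 ± 0.59) and Dsp (-4.23 ± 0.80), Pou2af1, a lymphocyte coactivator (-3.32 ± 0.62), and Atp1b1, a sodium pump subunit (-2.29 ± 0.45), lay on the other side. Cdh1 measured 4.33 with dioxane and 7.42 with TCDD in thymocytes, and 3.59 to 4.45 on the emigrant arrays. Its dioxane thymocyte value lies under the highest bacterial control of that array (4.72), and its emigrant values are at or near background. Its difference, and that of any gene in this position, is bounded by background. The probe sets of Igfbp4, Dsp and Atp1b1 differed in sign. None passed: limma called 0 of 12393 genes (smallest adjusted p = 1.00), with 97 at an unadjusted p under 0.05 (56 higher, 41 lower). The spread came from the emigrant arrays, and each lone thymocyte array was assumed to vary like them.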

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

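The tests weighed in this part were chosen after the results were seen. Differences of the TCDD effect between the sources drew attention because the estimate moved the other way or by a different size in emigrants and thymocytes. As medians over lists they were -1.39 for NK and innate lymphoid genes, 0.76 for fibroblast and endothelial genes and 0.75 for hypoxia and glycolysis genes, called by camera with a preset correlation. With an estimated correlation camera called none of them (adjusted p = 0.288, 0.726 and 0.288). Single genes were Clec4d (2.89), Ccl9 (3.17), Ccl6 (2.48), Apoe (1.66), Atp1b1 (-2.29), Igfbp4 (2.09) and Pou2af1 (-3.32), 7 of the 65 looked at. In thymocytes Apoe read 4.40 with TCDD and 4.51 with dioxane, under the highest bacterial controls there (4.46 and 4.72). A TCDD difference of Apoe could thus not be read in thymocytes. None of the 7 passed in limma (adjusted p = 1.00). Pou2af1 differed by 2.69 with TCDD in thymocytes and by -0.19 and -1.07 in emigrants numbered 1 and 2.

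The emigrant arrays numbered 1 stood apart from the other 4. Myeloid and erythroid cells in those samples could account for this. Against the emigrant arrays numbered 2, the neutrophil and mast cell list was higher by 1.42 and the DN2 and DN3 list differed by -1.17. These lists are part of what set the arrays apart, so they describe the pattern and do not test this account. Degraded RNA was argued against, since the 3' minus 5' signal of Gapdh differed by -0.174 and both arrays lay inside the range of the others. A shift between arrays left after RMA was also argued against. After cyclic loess 1418 genes still differed 2-fold between the dioxane emigrant arrays (1554 before it). Between dioxane emigrant array 2 and dioxane thymocytes 698 did. The RMA step itself was not varied. Whether more such cells left these lobes or were carried over in the flush stays open, and no biological explanation was tested.

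As a median, AHR targets hardly differed between the arrays numbered 1, though 3 of 15 were at least 2-fold higher with TCDD and 0 were that much lower. The list's median of 0.24 lay at percentile 96.87 of random lists, but this value is the pattern itself, so it decides nothing on whether the array labelled TCDD number 1 might hold cells cultured without TCDD. On the array labelled TCDD number 1, 10 of the 15 targets were higher than on the dioxane array and 5 lower. Scin, Cyp1b1, Xdh and Selenbp1 were among the higher ones. Clec4d differed by 2.84 there and by 2.91 between the arrays numbered 2. It was picked for its small p on these same emigrant arrays, so its agreement is no independent support. Fewer T-lineage cells in those samples could not be told apart from this: the targets' shortfall was 0.66 and the DN2 and DN3 deficit 1.17, with overlapping quartiles (0.06 to 2.12 and 0.28 to 2.28). Both stay open, and no biological explanation was tested.

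Rag1, Rag2 and Dntt were lower with TCDD in thymocytes and in emigrants numbered 2, with differences of -4.54, -1.45 and -4.80 as means of the 2 pairs. Rag1 read 3.61 on TCDD emigrant array 2 and Rag2 4.05 on the TCDD thymocyte array, under the highest bacterial controls there (4.34 and 4.46), so their differences are bounded by background, while Dntt read 5.61 and 9.10 on these arrays. By this mean the 19 other DN2 and DN3 genes fell less, with a median of -0.10 (quartiles -0.94 to 0.03, lowest -1.36). Within single pairs Rag2 did not stand below the rest. In emigrants numbered 2 it differed by -2.13 and Ptcra by -2.29. In thymocytes it differed by -0.77, a bound, and Bcl11b by -1.35. The 3 genes were picked after the results were seen and are the lowest of their list by the mean of the pairs. The gap to the other members therefore cannot decide whether a smaller share of such cells played a part. After cyclic loess of the RMA values the median of the 3 genes was -4.51. Cyclic loess shifts genes of like level together and could hardly remove so large a difference of single genes. It therefore speaks only against a shift between arrays left after RMA. A direct effect of TCDD on these genes, which the design names, stays open as an untested hypothesis.

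For TCDD over both sources, the real split of the 6 arrays gave 0 genes (659 at an unadjusted p under 0.05 in limma) and the highest other split gave 2. With 0 genes in the real split, 10 of the 10 splits into 3 and 3 reach it whatever the data, so their count decides nothing, and 10 splits are too few for a share under 0.1. At an unadjusted p under 0.05, 4 of the 9 other splits gave more genes than the real one: 1779, 1323, 1194 and 963. The split with 1323 sets both emigrant arrays numbered 1 and the TCDD thymocyte array against the rest.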

How the results depend on the processing

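The calls of gene lists depended on the test. Of 21 lists, camera with a preset correlation called 12 for TCDD in emigrants, 12 for TCDD over both sources, 7 between sources and 3 for the difference of effects. With an estimated correlation it called 0, 0, 0 and 0, and fry called 0, 0, 0 and 0. Leaving out 1 array gave 4 lists (without dioxane emigrant array 2) to 13 (without TCDD emigrant array 1) in emigrants, 9 (without dioxane emigrant array 2) to 15 (without dioxane emigrant array 1) over both sources, 4 (without dioxane emigrant array 2) to 8 (without the TCDD thymocyte array) between sources and 4 (without TCDD emigrant array 1) to 10 (without dioxane emigrant array 1) for the difference of effects. In emigrants, the DN2 and DN3 median ranged from -1.52 (without dioxane array 1) to 0.16 (without dioxane array 2), the cholesterol synthesis median from -1.21 (without dioxane array 1) to 0.0798 (without dioxane array 2), the neutrophil median from -0.39 (without TCDD array 1; -0.36 without dioxane array 2) to 1.21 (without TCDD array 2) and the interferon median from -0.38 (without TCDD array 2) to 1.37 (without TCDD array 1). Leaving out 1 array unbalances the numbers, so the TCDD difference then takes in part of the difference between numbers 1 and 2. That difference (number 1 minus number 2) was -1.17 for DN2 and DN3, -0.58 for cholesterol synthesis, 1.42 for neutrophil and -0.98 for interferon genes. The fibroblast, immediate-early and hypoxia lists kept their call in emigrants in each of the 4 omissions.

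Counts of called genes stayed at 0 with limma in each alternative for TCDD in emigrants (255 at an unadjusted p under 0.05; 250 without TCDD array 2 to 595 without dioxane array 2; 725 with the block, where 620 would come by chance). The same held for TCDD over both sources (659; 255 without either thymocyte array to 946 without dioxane emigrant array 1; 1334 with the block) and for the difference of effects (97; 103 without dioxane array 1 to 300 without dioxane array 2; 279 with the block). Between sources the count ran from 0 (without the TCDD thymocyte array) to 7 (without dioxane emigrant array 2), against 0 over all arrays (880 at an unadjusted p under 0.05; 344 without the dioxane and 382 without the TCDD thymocyte array, and 1025 without dioxane emigrant array 2). It was 225 with the 2 emigrant arrays numbered 2 left out and 160 in the replicate block model, which by construction compares the emigrants numbered 1 with the thymocytes; 135 genes were called in both. Same-numbered arrays deviated together from their group means (r = 0.560 across genes, over 2 pairs), but the labels do not say that the numbers mark pairs. Without the block this shared deviation stays in the residual spread and can hide TCDD differences. In emigrants 255 genes had an unadjusted p under 0.05 in limma without the block, and 725 with it. The replicate block gave 14 lists in emigrants, 15 over both sources, 9 between sources and 5 for the difference of effects. With the block, early progenitor (adjusted p = 0.0312) and gamma-delta T-cell genes (adjusted p = 0.00654) were gained in emigrants. Over both sources these (adjusted p = 0.0267 and 0.0019) and neutrophil genes (adjusted p = 0.0123) were gained. Between sources, early progenitor (adjusted p = 0.00704), gamma-delta (-1.11, adjusted p = 0.00468) and erythroid genes (adjusted p = 0.0359) were gained and adhesion genes lost (0.00, adjusted p = 0.568). For the difference of effects, adhesion (adjusted p = 0.0110) and neutrophil genes (adjusted p = 0.000168) were gained. No paired analysis was possible in thymocytes because each treatment had 1 array. A 1.5-fold threshold in thymocytes gave 1827 genes, against 697 at 2-fold. The same-sign share was 85% among the 100 genes with the smallest p, 63.2% at or above the median level and 57.8% over all genes. The genes chosen by the naming rule were refitted with their main probe set, and none changed sign in the alternatives run for it. Those of the thymocyte comparison were refitted in 3 alternatives, the normalisations. The filter at the median level left out the dimmer genes, and other probe sets of a gene were not part of this. List members named outside that rule, such as Ahrr and Rag1, were not refitted one by one.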

Other observations

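The genes in this part were chosen after their values were seen. Psat1, which makes serine, measured 9.34 with dioxane and 7.45 with TCDD in thymocytes, 9.78 and 8.14 in emigrants numbered 2, and 7.33 and 7.75 in emigrants numbered 1. Shmt2, which passes one-carbon units from serine to folate, differed by -2.35 in thymocytes, -0.77 in emigrants numbered 2 and 0.34 in emigrants numbered 1. Jchain, the immunoglobulin joining chain, measured 4.28 and 8.40 in thymocytes, 10.39 and 9.78 in emigrants numbered 1, and 3.90 and 4.08 in emigrants numbered 2.

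Neutrophil, macrophage and red-cell transcripts were among those that separated the emigrants numbered 1 from thymocytes when the arrays numbered 2 were left out, a model added after the data were seen. Lcn2 and Ngp, of neutrophils, were higher by 5.67 and 5.65. Rhag, a blood group protein, was higher by 4.60, Ermap, an erythroid membrane protein, by 4.50, and Car1, a carbonic anhydrase of red cells, by 5.93. Cd163, the hemoglobin scavenger receptor, was higher by 5.34, Slc40a1, the iron exporter of macrophages, by 5.77, and Vcam1, an adhesion molecule of erythroblastic island macrophages, by 4.75. In this model 10 of 19 neutrophil and mast cell genes, 11 of 21 macrophage genes and 2 of 10 erythroid genes were called higher, and 7 of 22 DN2 and DN3 genes lower. A beta-globin family probe set measured 13.36 and 13.43 on the arrays numbered 1, against 7.72 to 9.31 on the others.

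Eif2s3y, a gene on the Y chromosome, measured 3.35 on TCDD emigrant array 1 and 5.20 to 7.62 on the others. The value of 3.35 lies under the highest bacterial control of its array (4.92) and cannot be told from background.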
